A study of Mus musculus with 8 samples.

How the data were processed

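The data were 1 table of gene counts for 8 libraries of mouse liver endothelial cells in culture, 2 libraries in each of 4 groups (WT and dKO, each with and without IL1B and TNFA). The deposited values are raw read counts per Ensembl gene, whole numbers with a different total in each library, and no normalization was seen in them. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.7.6a and the genome build GRCm38 were used, without their roles being stated. The program that counted reads, the annotation release, any filter and the strand setting are not given in the sources used here. Per the labels' protocols, libraries were made with either an unstranded or a stranded kit, and which library used which is not stated, so counts of genes that overlap on opposite strands may be shared. Of 228 named or separately listed genes, 8 have at least 10% of their exon bases covered by a tested gene that reached 1 CPM or more, and are uncertain for that reason: Bak1, Bid, Ccnd1, Erap1, Fosl1, Lypd1, Pilra and Rarres2. Overlapping partners that were not tested were not weighed. Near-identical copies can also share counts, so the values of Ifit3 and Ifit3b, Saa2 and Saa3, Hspa1a and Hspa1b, the H2-Q genes, Apol9a and Sprr2e are uncertain. The labels place the 4-OHT treatment both in the culture medium and in mice, and this was not settled.

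Samples were grouped by the genotype and treatment in the labels, and replicate numbers were taken from the sample titles. Library totals ran from 23009062 to 26944030 counts. Of 52636 genes in the table, 52403 identifiers carried a symbol. Coordinates are from the GENCODE M21 annotation of GRCm38, counted from 1.

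In R 4.3.3, edgeR 4.0.16 was run on the deposited counts with TMM scaling, a filter on low counts by group, which left 15698 genes, and a robust quasi-likelihood fit with 1 coefficient for each of the 4 groups over all 8 libraries. This left 4 residual degrees of freedom, and the common biological coefficient of variation was 24.3%. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes in each of 5 contrasts and a threshold of 0.05. CPM values use the TMM-scaled library sizes. Where a group had 0 counts for a gene, the change is given as at least the ratio to a floor of 3 counts over that group. Where it had 1 to 3 counts, the ratio has a 95% counting interval. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

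The design, the alternative settings, the gene lists and the rule for named genes were written before the data were examined. The 24 lists were endothelial identity, liver sinusoidal endothelium, ETS family without the deleted genes, mesenchymal genes, TGF-beta and BMP response, Notch and arterial genes, venous and lymphatic endothelium, coagulation and vascular tone, leukocyte adhesion, chemokines and cytokines, NF-kB targets and feedback, interferon response, MHC antigen presentation, cell cycle, p53 and apoptosis, basement membrane, cell junctions, glycolysis and hypoxia, stress and immediate early genes, markers of stellate cells, pericytes and fibroblasts, of leukocytes, of hepatocytes and of cholangiocytes and mesothelium, and mitochondrial transcripts. Of 576 listed genes, 574 were in the table and 506 were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 120 tests. With the correlation estimated from these 8 libraries, 0 of the 39 list calls remained and the smallest adjusted p was 0.0852. The fry test, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, passed 30 of the 120. It kept 24 of the 39 camera calls and lost 15, among them the interferon response interaction (fry adjusted p = 0.0555). In 19 of the 120 tests the median, the mean and the direction of the camera test differed in sign, and 0 of these passed the threshold.

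Named genes were Erg and Fli1, and, in each contrast, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM in a group, no overlap between the libraries compared and a symbol that is not a provisional name. Further, they were the 3 largest changes past the threshold among the members of each list with at least 1 CPM in a group, or, where no member passed, the member with the highest mean. Genes outside this rule are said to have been chosen after their values were seen. Not every gene that the rule names is reported here.

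Libraries of the same number were checked for pairing by the correlation across genes of their deviations from the group means. Within a genotype it was 0.43 in WT and 0.69 in dKO. Across genotypes it was between 0.02 and 0.13. Xist and Y-linked transcripts also matched between libraries of the same number and genotype. The numbers were therefore taken to pair libraries within a genotype, from the data and not the labels, and values of a fit with genotype and number as a block (2 residual degrees of freedom) are given for the counts of changed genes, for list calls, and for a part of the named genes and list members whose call or count they change.

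The steps were tested on simulated counts for the same 15698 genes with 50 genes changed at each of 4 sizes. For dKO against WT without cytokines, 2%, 20%, 94% and 94% of the genes changed 1.5-, 2-, 4- and 8-fold were called, with 9 false calls. For the interaction with independent libraries, 0%, 16%, 70% and 92% were called, with 15 false calls. For the interaction with libraries of a culture shared between treatments, 0% of each size were called without the block and 22%, 90%, 100% and 100% with it. In this last case the culture effect and the spread within cultures were assumed, not estimated from these data. These shares therefore do not give the power of the paired fit here. A simulated changed list gave a camera p of 4.75e-26 for the interaction, and 0 of 100 unchanged lists had a p under 0.05. The genes were simulated independently of each other, so this does not test the preset correlation. In these data the estimated correlation of the interferon response list was 0.645 for the interaction.

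The alternatives were DESeq2 1.42.0 with its Wald test, its size factors in edgeR, no filter on low counts, an adjusted p of 0.01, a minimum change of 1.5-fold, the replicate number or genotype and number as a block, only the 4 libraries compared, and each library left out in turn. In the last case the lone library of a group is assumed to vary like the other groups. It is then also compared with libraries of both numbers, so a changed call can reflect the gap between replicates. Leaving out both dKO replicate 2 libraries, and the paired fit for the gene lists and their members, for named genes and for the genes shared by both cytokine responses, were added after seeing the data.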

Results

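Gene expression was measured by sequencing polyadenylated RNA from endothelial cells, the cells that line blood vessels, taken from mouse liver and kept in culture. The cells were labelled WT or dKO, an abbreviation that the labels do not expand. The study's design text names loss of the ETS transcription factor genes Erg, Fli1 or both, induced with 4-OHT, an active form of tamoxifen, for 48 hours and followed by 7 days of culture. Cells of each genotype were left without cytokines or received the inflammatory cytokines IL1B and TNFA 16 hours before lysis, which gave 4 groups of 2 libraries. Live cells positive for CD31 and VE-cadherin and negative for CD45 were sorted before RNA was prepared. The total counts were 23850223 and 26944030 in WT replicate 1 and 2 without cytokines, 23836723 and 25955438 in WT with cytokines, 23009062 and 23052865 in dKO without and 24652645 and 24055678 in dKO with cytokines. Of the 52636 genes in the deposited table, 15698 passed the filter on low counts and were tested. Nothing in the labels says that the 2 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples. Xist levels, given below, set the 2 libraries of each group further apart than technical repeats would be. Levels are given as CPM, counts scaled to the size of each library, as mean ± SD with n = 2, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

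Erg (ENSMUSG00000040732, GRCm38 chromosome 16, 95359169 to 95586593, minus strand) stood at 196 and 186 CPM in the WT libraries without cytokines and at 208 and 201 CPM in those with cytokines. In dKO replicate 1 it stood at 40.1 CPM without and 34.7 CPM with cytokines, and in dKO replicate 2 at 91.3 and 90.2 CPM. Fli1 (ENSMUSG00000016087, GRCm38 chromosome 9, 32422204 to 32542861, minus strand) stood at 161 and 177 CPM in WT without cytokines, at 91.5 and 96.4 CPM in WT with cytokines, at 21.9 and 12.4 CPM in dKO replicate 1 and at 62.5 and 35.2 CPM in dKO replicate 2. Every dKO library lay below every WT library with the same treatment for both genes. The fitted log2 fold changes of Erg were -1.54 (SE 0.53, adjusted p = 0.0864) without and -1.71 (SE 0.54, adjusted p = 0.0538) with cytokines, and those of Fli1 were -2.0 (SE 0.63, adjusted p = 0.0678) and -1.98 (SE 0.63, adjusted p = 0.0562). None of these 4 tests passed 0.05 in edgeR, and 4 did in DESeq2. The unadjusted p of Fli1 was 0.0191 without and 0.0204 with cytokines. Without both dKO replicate 2 libraries, an alternative chosen after seeing the data, all 4 passed. Without the dKO replicate 2 library lacking cytokines, Fli1 passed (adjusted p = 0.04). Without the one given cytokines, Erg (0.0261) and Fli1 (0.0389) passed. Counts are per gene and can include exons outside a deleted part, so remaining counts alone do not show how complete a deletion was.

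The dKO replicate 2 libraries stood apart from dKO replicate 1. On the first principal component, which held 57.1% of the variance, the WT libraries lay between -85.8 and -57.6, dKO replicate 1 at 102.2 without and 89.2 with cytokines, and dKO replicate 2 at 51.2 and 42.9. Xist, transcribed from the inactive X chromosome of female cells and chosen after its values were seen, stood at 0.48 CPM in WT replicate 1, 633 CPM in WT replicate 2, 0.849 CPM in dKO replicate 1 and 224 CPM in dKO replicate 2 without cytokines. The Y-linked Ddx3y, chosen in the same way, stood at 118, 0.0337, 140 and 90.6 CPM in those libraries. With cytokines Xist stood at 0.926, 454, 1.32 and 171 CPM in the same order.

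**Figure D1:**
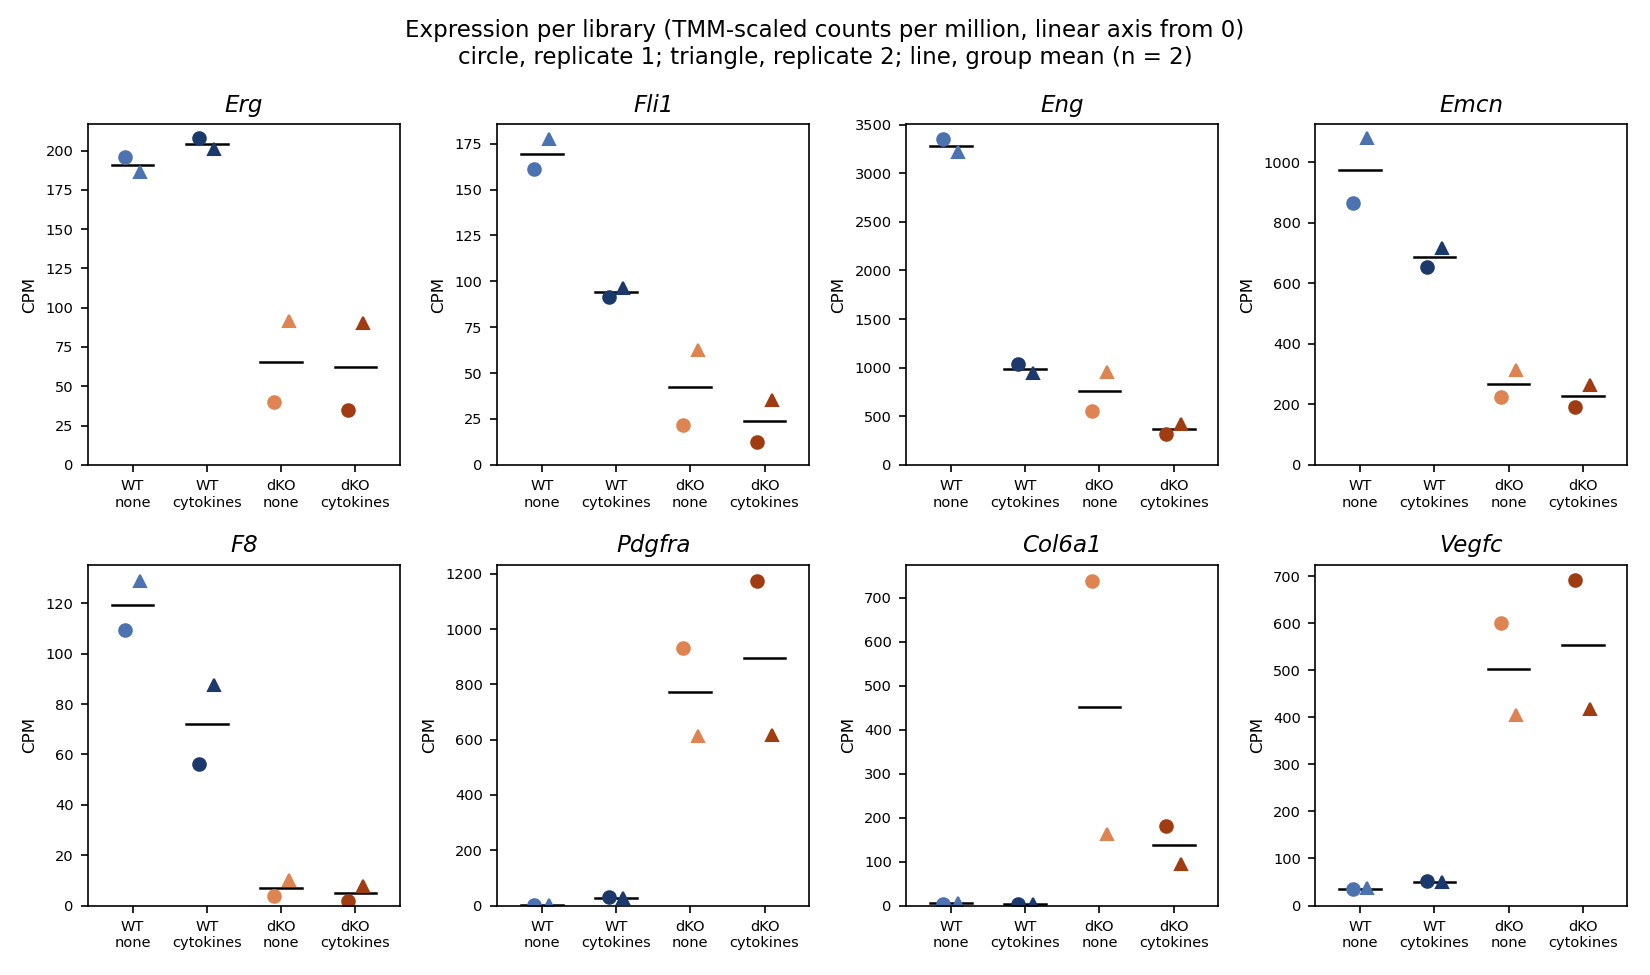
CPM of Erg, Fli1, Eng, Emcn, F8, Pdgfra, Col6a1 and Vegfc on linear axes from 0, with a circle for replicate 1, a triangle for replicate 2 and a line for the mean of the 2 libraries in each of the 4 groups. Erg in dKO replicate 2 (91.3 and 90.2 CPM) lay between WT (186 to 208 CPM) and dKO replicate 1 (40.1 and 34.7 CPM), and Pdgfra had means of 2.87 and 28.8 CPM in WT and of 774 and 895 CPM in dKO.

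The comparison of dKO with WT cells without cytokines addresses the effect of the deletion in resting cultures. The endothelial surface genes Eng and Emcn were lower in dKO cells. Eng (GRCm38 chromosome 2, 32646595 to 32682669), a co-receptor for TGF-beta family ligands, had 3280 ± 99.2 CPM in WT and 759 ± 284 CPM in dKO, 4.32-fold lower (log2 fold change -2.11, SE 0.27, adjusted p = 0.00565). Emcn, a sialomucin of endothelial cells, was 3.63-fold lower (974 ± 152 against 268 ± 63.7 CPM, log2 fold change -1.86, SE 0.23, adjusted p = 0.0052). Pdgfra (GRCm38 chromosome 5, 75152292 to 75198215), a growth factor receptor of mesenchymal cells, rose from 2.87 ± 1.14 to 774 ± 225 CPM, 268-fold (log2 fold change 8.07, SE 0.55, adjusted p = 0.00131). Vegfc, a ligand for lymphatic growth, rose 14.1-fold, from 35.6 ± 0.745 to 502 ± 138 CPM (log2 fold change 3.82, SE 0.30, adjusted p = 0.00163).

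Of the 37 endothelial identity genes, 8 were lower, 3 were higher and 26 did not pass, with 9 lower and 3 higher when adjusted over the list alone. DESeq2 called 13 lower and 3 higher. The log2 fold change was below 0 for 33 of the 37 and above 0 for 4. Vegfc, Eng and Emcn had the largest changes among the members that passed, and the median log2 fold change was -1.76. The list as a whole was lower than other genes (camera adjusted p = 4.17e-06), a call that was lost with an estimated correlation (adjusted p = 0.633). In the fry test it did not pass (adjusted p = 0.139). Of 22 tested genes of liver sinusoidal endothelium, 5 fell and 3 rose (8 and 4 adjusted over the list alone). Clec4g, a lectin of these cells, was 236-fold lower, the fatty acid transporter gene Cd36 31.6-fold lower, and F8, which encodes coagulation factor VIII, 17.2-fold lower, from 119 ± 13.7 to 6.9 ± 4.64 CPM (list adjusted p = 0.0124, and 0.467 as the adjusted p with an estimated correlation). The coagulation and vascular tone list had 7 lower and 2 higher members of 24, the same counts as adjusted over the list alone, among them Tfpi2, an inhibitor of serine proteases, 6.15-fold lower, and the thrombin receptor gene F2r, 11-fold higher (list adjusted p = 0.0124, adjusted p = 0.428 with an estimated correlation). In the leukocyte adhesion list 4 of 18 genes fell and 1 rose (6 and 1 adjusted over the list alone), with Alcam 3.64-fold, Ceacam1 3.49-fold and Pecam1 3.47-fold lower (list adjusted p = 0.0304, adjusted p = 0.559 with an estimated correlation).

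Of 29 mesenchymal genes, 10 rose and 1 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.58. The collagen genes Col6a1 and Col3a1 rose 87.1-fold and 42.2-fold, and the transcription factor gene Prrx1 62.4-fold (list adjusted p = 0.000922, adjusted p = 0.428 with an estimated correlation). In dKO replicate 1 and replicate 2, Col6a1 stood at 738 and 163 CPM and Col3a1 at 1830 and 332 CPM, against at most 27.2 CPM in WT. Among 12 tested markers of stellate cells, pericytes and fibroblasts, 4 rose and 0 fell (7 rose when adjusted over the list alone), with Pdgfra, Pdgfrb (16-fold) and Lum (6.13-fold) in front (list adjusted p = 0.00173, adjusted p = 0.291 with an estimated correlation). In WT, 9 of the 18 markers of that list were at 1 CPM or more, and Dcn, chosen for this comparison after its values were seen, had 9100 ± 106 CPM there. The cholangiocyte and mesothelial markers had 3 of 7 higher (5 adjusted over the list alone), which were Spp1 (51.9-fold), Sox9 (29.4-fold) and Cdh1 (5.2-fold; list adjusted p = 0.000758, adjusted p = 0.291 with an estimated correlation, and 0.0861 without the filter on low counts). In the hepatocyte list 3 of 5 tested members rose, also adjusted over the list alone. These were Ahsg (357-fold), Hp (68.9-fold) and Trf (6.42-fold), which encode secreted plasma proteins (list adjusted p = 0.0175, adjusted p = 0.4 with an estimated correlation). That list's adjusted p was 0.066 without dKO replicate 2 and 0.125 without the filter on low counts. Alb, the main hepatocyte transcript and chosen after its values were seen, had 0 counts in all 4 libraries without cytokines, which allows up to 0.0529 CPM in WT and 0.0646 CPM in dKO.

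Cell cycle genes were lower in dKO cells. Of 34, 21 fell and 1 rose (30 and 1 adjusted over the list alone), with a median log2 fold change of -1.19. Kif23, a kinesin of dividing cells, was 4.19-fold lower, the replication helicase gene Mcm5 4.04-fold lower and the proliferation marker Mki67 3.55-fold lower (list adjusted p = 3.95e-12, adjusted p = 0.4 with an estimated correlation). In the glycolysis and hypoxia list 14 of 26 genes rose and 0 fell (18 rose adjusted over the list alone). Vegfa, the main angiogenic growth factor gene, rose 7.75-fold, Egln3, an oxygen sensor gene, 4.06-fold and Ddit4 3.2-fold (list adjusted p = 7.2e-05, adjusted p = 0.4 with an estimated correlation).

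The other 14 lists did not pass in this comparison. The ETS family without the deleted genes had 1 member higher and 3 lower of 17 (Etv5 2.46-fold higher, Elf1 1.94-fold lower), the TGF-beta and BMP list 6 and 2 of 24 (Tgfbi 12-fold higher), and the Notch and arterial list 5 and 3 of 17 (Mgp 87.4-fold and the connexin gene Gja4 11.1-fold higher, Notch1 2.94-fold lower). Venous and lymphatic genes had 1 higher and 2 lower of 15 (von Willebrand factor gene Vwf 2.44-fold lower, list adjusted p = 0.0656), chemokines and cytokines 9 and 3 of 32 (Cxcl12 120-fold and Il33 78.7-fold higher, and Ccl8 at least 44.4-fold higher), and NF-kB targets 12 and 5 of 33 (Tnfaip2 7.09-fold and Tnfaip8 6.04-fold higher). Interferon response genes had 2 higher and 3 lower of 40 (Zbp1 21.9-fold higher, Bst2 3.13-fold lower, list adjusted p = 0.0583), and MHC antigen presentation genes 2 and 1 of 23 (H2-Ab1 49.3-fold higher). The p53 and apoptosis list had 4 higher and 2 lower of 27, basement membrane 3 and 2 of 20, cell junctions 4 and 5 of 25 (Esam 3.44-fold lower), and stress and immediate early genes 3 and 4 of 25. Of 8 leukocyte markers 0 passed in edgeR, 1 had an unadjusted p under 0.05 and 1 passed in DESeq2, and Cd14 stood at 318 ± 102 CPM in WT and 197 ± 1.64 CPM in dKO (adjusted p = 0.0669). Of 7 mitochondrial transcripts 0 passed in edgeR, at an unadjusted p under 0.05 or in DESeq2. Some of these list calls changed with the setting or without 1 library. Without the filter on low counts, venous genes (adjusted p = 0.0323) and interferon genes (0.0256) passed downward, and chemokines and cytokines upward with the replicate number as a block (0.0221). Venous genes had an adjusted p of 0.00608 without WT replicate 2, 0.0259 without dKO replicate 2, and 0.0382 and 0.0442 without dKO replicate 1 or 2 given cytokines. Interferon genes had 0.0146 without WT replicate 1, 0.0295 without dKO replicate 1, and 0.00809 and 0.00589 without WT replicate 1 or 2 given cytokines. Chemokines and cytokines had 0.00617 without dKO replicate 1.

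The genes with the largest rises by the naming rule included Has2, a hyaluronan synthase gene, with 0 counts in WT and 655 in dKO (at least 267-fold higher against a floor of 3 counts over the group), the transcription factor gene Myb (at least 163-fold) and the amino acid transporter gene Slc36a2 (at least 51.7-fold). The neurotrophin receptor gene Ntrk3 had 1 count in WT and 463 in dKO, a ratio of 566 with a 95% counting interval from 101 to 22400, and Rarres2 had 2 and 695 counts, a ratio of 425 with an interval from 117 to 3510. The matrix gene Fbln1 rose 433-fold (1980 CPM in dKO replicate 1 and 641 CPM in replicate 2), Saa2 429-fold and Aspg 379-fold. The largest falls, after Clec4g, were Chrdl1 (96.1-fold), Elavl2 (32.3-fold), Bcan (18.5-fold), Ehd3 (17.8-fold), F8, Cdh4 (15.2-fold) and Prss16 (15.1-fold), with adjusted p-values from 0.00129 for Cdh4 to 0.0445 for Bcan. In all, 3617 genes changed, 2101 higher and 1516 lower, and 2266 when only the 4 libraries compared were fitted. Of 77 named genes with a call, 29 kept it without each of the 4 libraries in turn. The count was 527 without WT replicate 1, 685 without WT replicate 2, 1180 without dKO replicate 1, and 5602 without both dKO replicate 2 libraries, the last chosen after seeing the data.

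The comparison of cytokine-treated with untreated WT cells addresses the inflammatory response of cells with both factors. Of the interferon response genes 38 of 40 rose, and of the chemokine and cytokine genes 22 of 32. Cxcl10 (GRCm38 chromosome 5, 92346638 to 92348889), a chemokine for T cells, rose from 0.643 ± 0.283 to 314 ± 264 CPM (480-fold, log2 fold change 8.91, SE 0.89, adjusted p = 0.00409), with 500 CPM in replicate 1 and 127 CPM in replicate 2. Ccl5 rose 251-fold to 163 ± 37.3 CPM (log2 fold change 7.97, SE 0.57, adjusted p = 0.0019), and Ptgs2, which encodes the inducible cyclooxygenase, rose from 39.3 ± 1.29 to 1660 ± 267 CPM, 42.1-fold (log2 fold change 5.40, SE 0.45, adjusted p = 0.00236). Eng fell 3.31-fold (log2 fold change -1.73, SE 0.27, adjusted p = 0.0104). Fli1 had a log2 fold change of -0.85 (adjusted p = 0.386), and passed with libraries of the same number paired within genotype (SE 0.08, adjusted p = 0.000101).

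Of 40 interferon response genes, 38 rose and 0 fell, the same as adjusted over the list alone, with a median log2 fold change of 3.67. The antiviral genes Mx1 and Zbp1 rose 155-fold and 103-fold, and Oas2 had 1 count without and 132 with cytokines, a ratio of 156 with a 95% counting interval from 27.4 to 6190 (list adjusted p = 1.45e-30, adjusted p = 0.4 with an estimated correlation). Of 33 NF-kB targets and feedback genes, 26 rose and 1 fell (28 and 1 adjusted over the list alone), among them Tnip3 (33.6-fold), Tnfaip2 (21.7-fold) and the kinase gene Ripk2 (17-fold; list adjusted p = 7.96e-24, adjusted p = 0.0852 with an estimated correlation). Of 32 chemokine and cytokine genes, 22 rose and 0 fell (25 adjusted over the list alone), with Cxcl11 at least 68.8-fold higher and Cxcl9 at 1 and 369 counts, a ratio of 435 with an interval from 77.6 to 17200 (list adjusted p = 2.26e-22, adjusted p = 0.138 with an estimated correlation). Of 23 MHC antigen presentation genes, 20 rose and 0 fell (22 adjusted over the list alone), with H2-Ab1 15-fold, H2-Q7 11.8-fold and the checkpoint ligand gene Cd274 10.8-fold higher (list adjusted p = 3.43e-17, adjusted p = 0.4 with an estimated correlation).

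Leukocyte adhesion genes had 7 of 18 higher and 0 lower, also adjusted over the list alone. E-selectin gene Sele rose 11.7-fold to 5200 ± 1070 CPM, the addressin gene Madcam1 11-fold and Cd44 8.42-fold (list adjusted p = 0.00824, adjusted p = 0.492 with an estimated correlation). In the glycolysis and hypoxia list 15 of 26 rose and 1 fell (19 and 1 adjusted over the list alone), with Eno2 3.12-fold, Pfkfb3 2.87-fold and the lactate transporter gene Slc16a3 2.49-fold higher (list adjusted p = 8.05e-08, adjusted p = 0.291 with an estimated correlation). Stress and immediate early genes had 5 of 25 higher and 0 lower (9 adjusted over the list alone), with Hspa1b 5.44-fold, Jund 2.58-fold and Ier3 2.43-fold higher (list adjusted p = 0.0124, adjusted p = 0.595 with an estimated correlation, and 0.0548 without WT replicate 2 lacking cytokines). Liver sinusoidal endothelial genes had 3 of 22 lower and 0 higher, also adjusted over the list alone, with Clec4g 211-fold, the Wnt enhancer gene Rspo3 2.24-fold and the transcription factor gene Gata4 2.2-fold lower. The adjusted p of that list was 0.0288, or 0.559 with an estimated correlation, 0.139 without WT replicate 1 lacking cytokines and 0.123 without WT replicate 2 with cytokines. With libraries of the same number paired within genotype, 10 adhesion genes rose and 4 fell, 12 stress genes rose and 4 fell, and 2 sinusoidal genes rose and 9 fell.

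Among the lists that did not pass, the arterial kinase gene Bmx fell 12.7-fold and Fbln5 5.48-fold, the 2 of 17 Notch and arterial genes that changed (list adjusted p = 0.158, and 0.0287 with libraries of the same number paired within genotype). In the coagulation list 4 genes rose and 7 fell of 24 (list adjusted p = 0.135, and 0.0477 without dKO replicate 1 given cytokines), with Ptgs1 4.72-fold lower. Selp rose 3.16-fold to 11700 ± 726 CPM and Lrg1 fell 4.49-fold in the venous list. Tgfb2 fell 10.7-fold among the mesenchymal genes, of which 5 rose and 2 fell. Pdgfra and Pdgfrb rose 9.99-fold and 6.6-fold while Bgn fell 1.89-fold, the 3 of 12 stromal markers that changed (list adjusted p = 0.313). In the p53 and apoptosis list 5 rose and 1 fell of 27, with the death receptor gene Fas 5.79-fold higher. Agrn rose 9.43-fold in the basement membrane list, and Amotl2 fell 4.21-fold in the cell junction list. With libraries paired within genotype, 2 genes rose and 8 fell in the Notch and arterial list, 6 and 14 in the coagulation list, 9 and 8 in the mesenchymal list, 7 and 7 in the p53 list, 3 and 2 among the stromal markers and 7 and 12 of the endothelial identity genes, of which 0 rose and 3 fell unpaired.

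By the naming rule the largest rises were Has2 (at least 71.9-fold), Cxcl10, Ccl5, Sprr2e (219-fold), Mx1, Pilra (137-fold), the hexose transporter gene Slc2a6 (112-fold) and the cytokine gene Tslp (112-fold, from 10.8 ± 4.01 to 1200 ± 398 CPM). The largest falls were Crh (at least 27.7-fold), Clec4g, Dnah11 (at least 8.2-fold), Gdpd2 (41.9-fold), the retinoic acid hydroxylase gene Cyp26b1 (35.2-fold) and Aox3 (27.1-fold). Mlxipl had 77 counts without and 2 with cytokines, a ratio of 32.7 with a counting interval from 8.74 to 275, and Vegfd 74 and 2 counts, a ratio of 31.4 with an interval from 8.39 to 264. In all, 2733 genes changed, 1526 higher and 1207 lower, and 5943 with libraries of the same number paired within genotype. Of 69 named genes with a call, 21 kept it without each of the 4 libraries in turn. The count was 413 and 513 without WT replicate 1 or 2 lacking cytokines, and 628 and 993 without WT replicate 1 or 2 given cytokines.

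**Figure D2:**
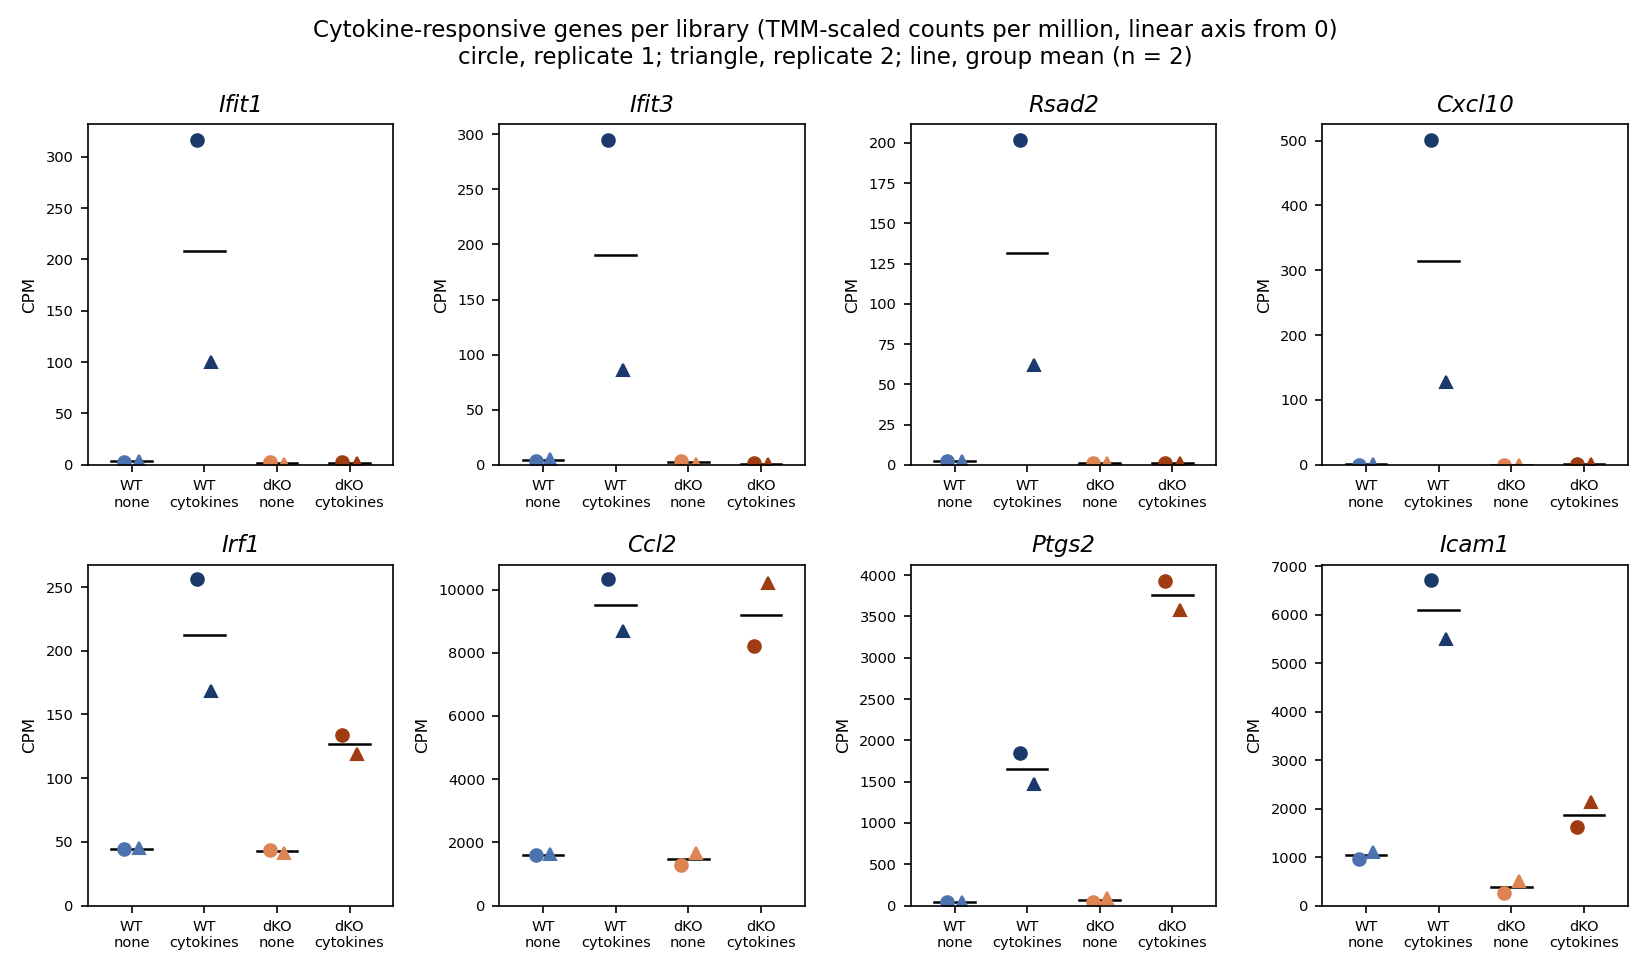
CPM of Ifit1, Ifit3, Rsad2, Cxcl10, Irf1, Ccl2, Ptgs2 and Icam1 on linear axes from 0, with a circle for replicate 1, a triangle for replicate 2 and a line for the mean of the 2 libraries in each of the 4 groups. With cytokines Ifit1 stood at 316 and 100 CPM in WT and at 2.73 and 1.46 CPM in dKO, while mean Ccl2 was 9510 CPM in WT and 9210 CPM in dKO.

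In dKO cells, the same comparison addresses the response that is left after the deletion. Ptgs2 (GRCm38 chromosome 1, 150100031 to 150108227) rose from 66.4 ± 38.1 to 3760 ± 247 CPM, 56.6-fold (log2 fold change 5.82, SE 0.46, adjusted p = 0.00516). Ccl5 rose 152-fold to 40.2 ± 11.4 CPM (log2 fold change 7.25, SE 0.61, adjusted p = 0.00601), and Clec4e, a pattern recognition receptor gene, rose 43.5-fold to 304 ± 15.8 CPM (log2 fold change 5.44, SE 0.28, adjusted p = 0.00407). Tnfaip3, a brake on NF-kB signalling, rose 6.89-fold (log2 fold change 2.78, SE 0.30, adjusted p = 0.0105). These genes and Pilra were the 5 of 47 named genes with a call that kept it without each of the 4 dKO libraries in turn.

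NF-kB targets and feedback genes had 23 of 33 higher and 1 lower (27 and 3 adjusted over the list alone), with Tnip3 17-fold and the receptor gene Nod2 6-fold higher (list adjusted p = 2.45e-23, adjusted p = 0.0852 with an estimated correlation). Chemokines and cytokines had 14 of 32 higher and 0 lower (21 adjusted over the list alone), with Tslp 34.8-fold and Lif 24.4-fold higher after Ccl5 (list adjusted p = 4.1e-22, adjusted p = 0.138 with an estimated correlation). The median log2 fold change of that list was 2.53, or 2.36 with genes at 0 set to their bound. MHC antigen presentation genes had 3 of 23 higher and 0 lower (12 adjusted over the list alone), namely Psmb10 (2.78-fold), Erap1 (1.81-fold) and the chaperone gene Calr (1.6-fold; list adjusted p = 2.12e-09, adjusted p = 0.452 with an estimated correlation). In the interferon response list 1 of 40 genes rose and 0 fell, also adjusted over the list alone, which was Irf1, from 42.5 ± 1.5 to 127 ± 10.5 CPM (2.98-fold, adjusted p = 0.0136). The median of that list was 0.17 (list adjusted p = 0.136), with adjusted p-values of 0.0495 and 0.0492 without WT replicate 1 or 2 given cytokines and 0.0482 without dKO replicate 2 given cytokines. With libraries paired within genotype, 22 chemokine and cytokine genes rose and 2 fell, 14 MHC genes rose, and 4 interferon response genes rose (1 adjusted over the list alone).

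Glycolysis and hypoxia genes had 4 of 26 higher and 0 lower (8 adjusted over the list alone), with Ddit4 3.02-fold, Ero1l 2.87-fold and the glucose transporter gene Slc2a1 1.95-fold higher (list adjusted p = 0.00186, adjusted p = 0.432 with an estimated correlation). Stress and immediate early genes had 4 of 25 higher and 0 lower (10 higher and 1 lower adjusted over the list alone), with Fosl1 3.35-fold, Jun 2.96-fold and Jund 1.76-fold higher (list adjusted p = 0.00255, adjusted p = 0.512 with an estimated correlation). Leukocyte adhesion genes had 4 of 18 higher and 0 lower (6 and 2 adjusted over the list alone), with Cd44 10.6-fold, Icam1 4.91-fold and Vcam1 2.97-fold higher. That list's adjusted p was 0.0307, or 0.57 with an estimated correlation, 0.119 without dKO replicate 1 lacking cytokines and 0.113 without dKO replicate 2 given them. In the p53 and apoptosis list only Gdf15, a stress-induced cytokine gene, passed of 27, also adjusted over the list alone, 10-fold higher. That list's adjusted p was 0.0157, or 0.633 with an estimated correlation, 0.21 without dKO replicate 1 lacking cytokines and 0.0521 without dKO replicate 2 given them. With libraries paired within genotype, 10 glycolysis genes rose, 9 stress genes rose and 2 fell, 9 adhesion genes rose and 3 fell, and 8 p53 and apoptosis genes rose and 2 fell.

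Endothelial identity genes had 0 of 37 higher and 2 lower, Bmx and Vwf (list adjusted p = 0.713). That list was lower without dKO replicate 1 lacking cytokines and without dKO replicate 2 given them, and higher without dKO replicate 2 lacking cytokines. Those fits leave a dKO library without its partner, so the shifts cannot be told apart from the gap between the dKO replicates. With libraries paired within genotype the list adjusted p was 0.471. Among the other lists that did not pass, Bmx fell 7.43-fold and Nrp1 2.01-fold in the Notch and arterial list, Vwf 2.39-fold in the venous list, and Procr rose 2.89-fold in the coagulation list. Inhba rose 2.58-fold and Tgfbr2 fell 2.12-fold, the 2 of 24 TGF-beta and BMP genes that changed (list adjusted p = 0.705, and 0.0206 with libraries paired within genotype). Tyms and Ccne1 rose 2.66-fold and 2.12-fold in the cell cycle list, and the connexin gene Gja1 rose 2.77-fold in the cell junction list. In edgeR 0 of 22 sinusoidal endothelial genes, 0 of 17 ETS family genes and 0 of 12 stromal markers passed. Of these, 2, 3 and 0 had an unadjusted p under 0.05, and 0 of each list passed in DESeq2. With libraries paired within genotype, 2 sinusoidal genes rose and 7 fell, 6 ETS family genes rose and 1 fell, and 1 stromal marker rose. In that fit 6 endothelial identity genes rose and 7 fell, as did 4 and 9 coagulation genes, 5 and 7 mesenchymal genes, 8 and 8 TGF-beta and BMP genes, 2 and 4 Notch and arterial genes, and 5 and 2 cell cycle genes. The sinusoidal list had an adjusted p of 0.317, and of 0.043 without dKO replicate 1 lacking cytokines. Eng and Fli1 had log2 fold changes of -1.04 (adjusted p = 0.0764) and -0.83 (adjusted p = 0.487), and both passed in the paired fit (adjusted p = 0.00104 and 0.000397). Dcn stood at 12600 ± 1220 CPM without and 14100 ± 1040 CPM with cytokines.

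By the naming rule the largest rises after those named were Penk (37.2-fold), Tslp and the nitric oxide synthase gene Nos2 (34.3-fold). Sprr2e had 3 counts without and 1883 with cytokines, a ratio of 653 with a 95% counting interval from 223 to 3170, and Pilra was at least 25.3-fold higher. The largest falls were Crh (31.3-fold), Ccn5 (15.7-fold), Plin4 (14.3-fold), Vegfd (12.1-fold), Lypd1 (11.7-fold), Ildr2 (9.33-fold), the keratin gene Krt18 (9.2-fold) and Svep1 (7.8-fold), with adjusted p-values from 0.0078 for Svep1 to 0.047 for Plin4. In all, 872 genes changed, 549 higher and 323 lower, and 3769 with libraries of the same number paired within genotype. The count was 130 without dKO replicate 1 lacking cytokines, 190 without dKO replicate 1 given cytokines, 1734 in DESeq2 and 1 when only the 4 dKO libraries were fitted.

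The comparison of dKO with WT cells, both given cytokines, addresses the state of the inflamed cells. Interferon-induced genes were lower in dKO cells. Ifit1 (GRCm38 chromosome 19, 34640871 to 34650009) stood at 208 ± 153 CPM in WT and 2.09 ± 0.897 CPM in dKO, 99.4-fold lower (log2 fold change -6.63, SE 0.78, adjusted p = 0.00388). Rsad2, which encodes the antiviral enzyme viperin, was 122-fold lower (log2 fold change -6.93, SE 0.67, adjusted p = 0.00254), and Cxcl10 200-fold lower (log2 fold change -7.64, SE 0.83, adjusted p = 0.00336). Pdgfra was 31.1-fold higher in dKO, at 895 ± 395 against 28.8 ± 4.83 CPM (log2 fold change 4.96, SE 0.47, adjusted p = 0.00232), and the angiopoietin co-receptor gene Tie1 was 3.56-fold lower (log2 fold change -1.83, SE 0.28, adjusted p = 0.00613).

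Of 40 interferon response genes, 37 were lower and 0 higher (38 lower adjusted over the list alone), with Ifit3b 248-fold, Ifit3 176-fold and Rsad2 122-fold lower (list adjusted p = 2.45e-23, adjusted p = 0.432 with an estimated correlation). The median log2 fold change was -3.36. MHC antigen presentation genes had 11 of 23 lower and 1 higher (13 and 1 adjusted over the list alone), with Cd274 5.21-fold and the peptide transporter gene Tap1 4.17-fold lower and H2-Ab1 6.6-fold higher (list adjusted p = 0.000964, adjusted p = 0.641 with an estimated correlation, and 0.064 without both dKO replicate 2 libraries). Leukocyte adhesion genes had 7 of 18 lower and 0 higher, also adjusted over the list alone, with Madcam1 12.6-fold, Sele 9.33-fold and Selp 4.17-fold lower (list adjusted p = 0.00385, adjusted p = 0.452 with an estimated correlation). Chemokines and cytokines had 6 higher and 9 lower of 32 (7 and 9 adjusted over the list alone), with Cxcl11 at least 54.1-fold lower and Cxcl12 146-fold higher, and the list did not pass (adjusted p = 0.609). NF-kB targets had 6 higher and 9 lower of 33 (7 and 10 adjusted over the list alone), with Nod2 8.51-fold and Ripk2 4.09-fold lower, and did not pass either (adjusted p = 0.329).

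Endothelial identity genes had 6 of 37 lower and 3 higher, also adjusted over the list alone, with Vegfc 10.9-fold and Bmx 4.3-fold higher (list adjusted p = 0.000967, adjusted p = 0.73 with an estimated correlation). Cell cycle genes had 19 of 34 lower and 2 higher (22 and 2 adjusted over the list alone), with Mki67 6.63-fold, Mcm5 4.09-fold and Mcm3 3.81-fold lower (list adjusted p = 9.1e-07, adjusted p = 0.467 with an estimated correlation). Stromal markers had 4 of 12 higher and 0 lower, also adjusted over the list alone, with Lum 7.39-fold and Bgn 3.71-fold higher after Pdgfra (list adjusted p = 0.0148, adjusted p = 0.4 with an estimated correlation). In dKO replicate 1 and replicate 2, Lum stood at 1310 and 487 CPM. Cholangiocyte and mesothelial markers had 3 of 7 higher, also adjusted over the list alone, with Spp1 214-fold, Sox9 13.8-fold and Cdh1 6.02-fold higher (list adjusted p = 0.00635, adjusted p = 0.365 with an estimated correlation). Hepatocyte markers had 3 of 5 higher, also adjusted over the list alone, again Ahsg (396-fold), Hp (35.3-fold) and Trf (12.4-fold; list adjusted p = 0.0157, adjusted p = 0.4 with an estimated correlation, and 0.101 without both dKO replicate 2 libraries). Both of these lists had an adjusted p of 0.117 without the filter on low counts.

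In lists that did not pass, Prrx1 rose 118-fold and Col1a2 36.8-fold among 13 higher and 3 lower mesenchymal genes of 29. That list's adjusted p was 0.0656, and 0.0483 and 0.00567 without dKO replicate 1 lacking or given cytokines. Without dKO replicate 2 given cytokines, the venous list had an adjusted p of 0.0462, against 0.126, and the cell junction list of 0.0482, against 0.173. Vegfa rose 6.81-fold, Ddit4 5.21-fold and Ero1l 4.28-fold, with 8 higher and 5 lower of 26 glycolysis and hypoxia genes. Gdf15 was 28.3-fold higher in the p53 list, F8 14.7-fold and Maf 8.18-fold lower in the sinusoidal list, and Jag1 4.86-fold lower in the Notch list. Nog, a BMP antagonist gene, was 57.1-fold higher. Cd14 was 3.52-fold lower, the only leukocyte marker of 8 that passed, and mt-Cytb 1.42-fold lower, the only mitochondrial transcript of 7.

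By the naming rule the largest rises were Tesc (0 against 972 counts, at least 349-fold), Dnah11 (at least 83-fold), Avpr1a and Ntrk3 (at least 32.3-fold each), Fbln1 (411-fold), Ahsg and the sphingosine phosphate receptor gene S1pr3 (301-fold). Cnmd had 1 and 547 counts, a ratio of 590 with a 95% counting interval from 105 to 23300. The largest falls were the interferon-induced genes named above with Oas3 (99.2-fold) and Apol9a (81.7-fold), and Chrdl1, with 250 and 1 counts, a ratio of 232 with an interval from 41.2 to 9190. In all, 5343 genes changed, 2926 higher and 2417 lower, and 3798 when only the 4 libraries compared were fitted. Of 75 named genes with a call, 44 kept it without each of the 4 libraries in turn. The count was 1621 and 2306 without WT replicate 1 or 2, and 2362 without dKO replicate 1.

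**Figure D3:**
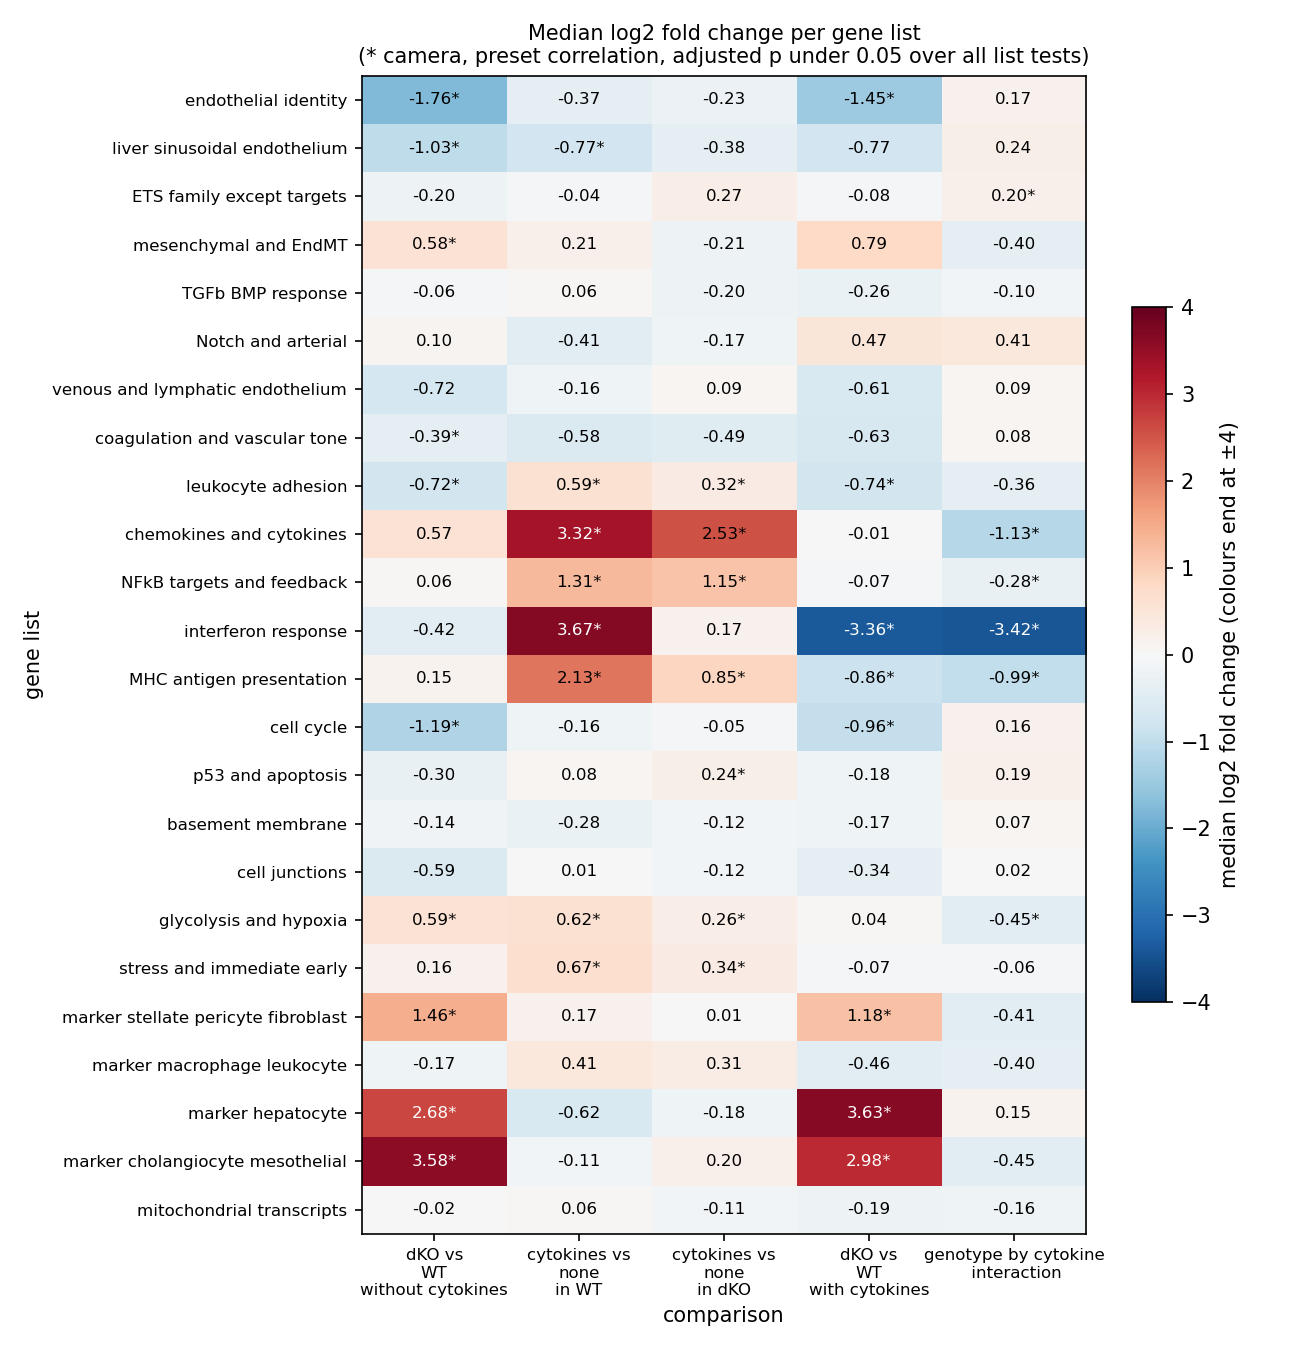
Median log2 fold change of the tested members of each of the 24 gene lists (vertical) in each of the 5 comparisons (horizontal), with colours ending at 4 in either direction and an asterisk where the camera test with a preset correlation passed an adjusted p of 0.05. The interferon response list had a median of 3.67 for cytokines in WT, 0.17 for cytokines in dKO and -3.42 for the interaction.

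The interaction tests whether the response to cytokines itself differed between genotypes. Interferon response genes rose less in dKO than in WT cells as a list, with 40 of 40 interaction terms below 0, a median of -3.42 on the log2 scale, and 37 members past the threshold when adjusted over the list alone (list adjusted p = 6.21e-54, adjusted p = 0.291 with an estimated correlation). The terms of Ifit1 (-5.82, SE 1.00, adjusted p = 0.193), Rsad2 (-5.59, SE 0.91, adjusted p = 0.187) and Cxcl10 (-6.44, SE 1.68, adjusted p = 0.285), genes that the rule names in other comparisons, did not pass over all genes tested. With libraries paired within genotype their adjusted p-values were 0.0947, 0.106 and 0.222, and 5 of the 40 interferon genes passed below 0 over all genes tested, or 35 adjusted over the list alone. MHC antigen presentation genes had a median of -0.99, with 7 of 23 past when adjusted over the list alone (list adjusted p = 1.45e-10, adjusted p = 0.432 with an estimated correlation), NF-kB targets -0.28 with 6 of 33 (4.17e-06, adjusted p = 0.291 with an estimated correlation), glycolysis and hypoxia genes -0.45 with 3 of 26 (0.000219, adjusted p = 0.4 with an estimated correlation), and chemokines and cytokines -1.13 with 5 lower and 1 higher of 32 (0.000332, adjusted p = 0.428 with an estimated correlation). Among them Ccl2, a monocyte chemokine gene, had a term of 0.08 (SE 0.28, adjusted p = 0.96), Tnfaip2 of -2.11 (SE 0.34, adjusted p = 0.182) and Calr of -0.16 (SE 0.15, adjusted p = 0.771). In the paired fit Tnfaip2 passed (-2.14, SE 0.17, adjusted p = 0.00185). Over all genes tested that fit called 5 MHC genes lower, 7 NF-kB targets lower and 1 higher, 9 glycolysis and hypoxia genes lower and 2 higher, and 10 chemokine and cytokine genes lower and 2 higher.

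The ETS family without the deleted genes had a median interaction of 0.20 with 0 of 17 members past the threshold in edgeR, 1 at an unadjusted p under 0.05 and 0 in DESeq2 (list adjusted p = 0.0493, adjusted p = 0.452 with an estimated correlation). Its adjusted p was above 0.05 without WT replicate 1 (0.0662) or replicate 2 (0.0809) lacking cytokines, WT replicate 1 given cytokines (0.119), dKO replicate 1 lacking cytokines (0.177) and dKO replicate 2 given cytokines (0.136). Endothelial identity genes had a median of 0.17 (list adjusted p = 0.26, and 0.16 with libraries paired within genotype). The list shifted upward without dKO replicate 2 lacking cytokines or dKO replicate 1 given them. Those fits leave a dKO library without its partner, so the shift cannot be told apart from the gap between the dKO replicates. Eng had a term of 0.69 (SE 0.37, adjusted p = 0.586), and of 0.73 with libraries paired within genotype (SE 0.17, adjusted p = 0.0484). The Notch and arterial list did not pass (adjusted p = 0.41), and did with libraries paired within genotype (0.045) or without dKO replicate 1 given cytokines (0.0477). Without dKO replicate 2 lacking cytokines, cell cycle (0.0085), p53 (0.0177), sinusoidal (0.0187) and coagulation genes (0.0457) passed upward. Without dKO replicate 1 given them, cell cycle (0.00248) and sinusoidal genes (0.0239) did. Mesenchymal genes (adjusted p = 0.0656) passed downward without WT replicate 2 lacking cytokines (0.00954), WT replicate 1 given cytokines (0.00979) or dKO replicate 2 given cytokines (0.0352). Leukocyte adhesion genes did without dKO replicate 1 lacking cytokines (0.00668), and mitochondrial transcripts without WT replicate 1 lacking cytokines (0.0299). With genes at 0 set to their bound, the median of the stromal markers moved from -0.41 to -0.84 and that of the cholangiocyte markers from -0.45 to -0.60. In edgeR 0 genes had an interaction at an adjusted p of 0.05, and 1683 genes had an unadjusted p under 0.05, against 785 expected by chance. DESeq2 called 372 genes, edgeR with libraries of the same number paired within genotype 947, and edgeR without both dKO replicate 2 libraries 193. Leaving out WT replicate 2 or dKO replicate 2 given cytokines gave 41 and 15 genes.

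Across the 15698 genes, which are not independent replicates, the log2 fold changes for cytokines in WT and in dKO correlated with Pearson r = 0.613 and Spearman rho = 0.582. The 2 comparisons share no library. Of the genes that rose, 426 rose in both, where independent lists of 1526 and 549 genes would share 53.4, and 250 fell in both, against 24.8. There were 2 genes with opposite calls. Without the filter on low counts r was 0.201, and 0.255 in DESeq2. Both shared counts fell whichever library was left out, which leaves 1 library in a group and fewer residual degrees of freedom. In each case the counts stayed above what independent lists would share, which does not tell whether 1 library weighed more than others. Without WT replicate 1 or 2 lacking cytokines, 89 and 97 genes rose and 41 and 46 fell in both, and without WT replicate 1 or 2 given them 139 and 158 rose and 59 and 66 fell. Without dKO replicate 1 lacking or given cytokines, 77 and 134 rose and 48 and 48 fell, and without dKO replicate 2 lacking cytokines 278 rose and 186 fell. DESeq2 gave 695 and 519. With libraries paired within genotype 1417 rose and 1239 fell in both, where independent lists would share 385 and 329, and 60 genes had opposite calls.

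**Figure D4:**
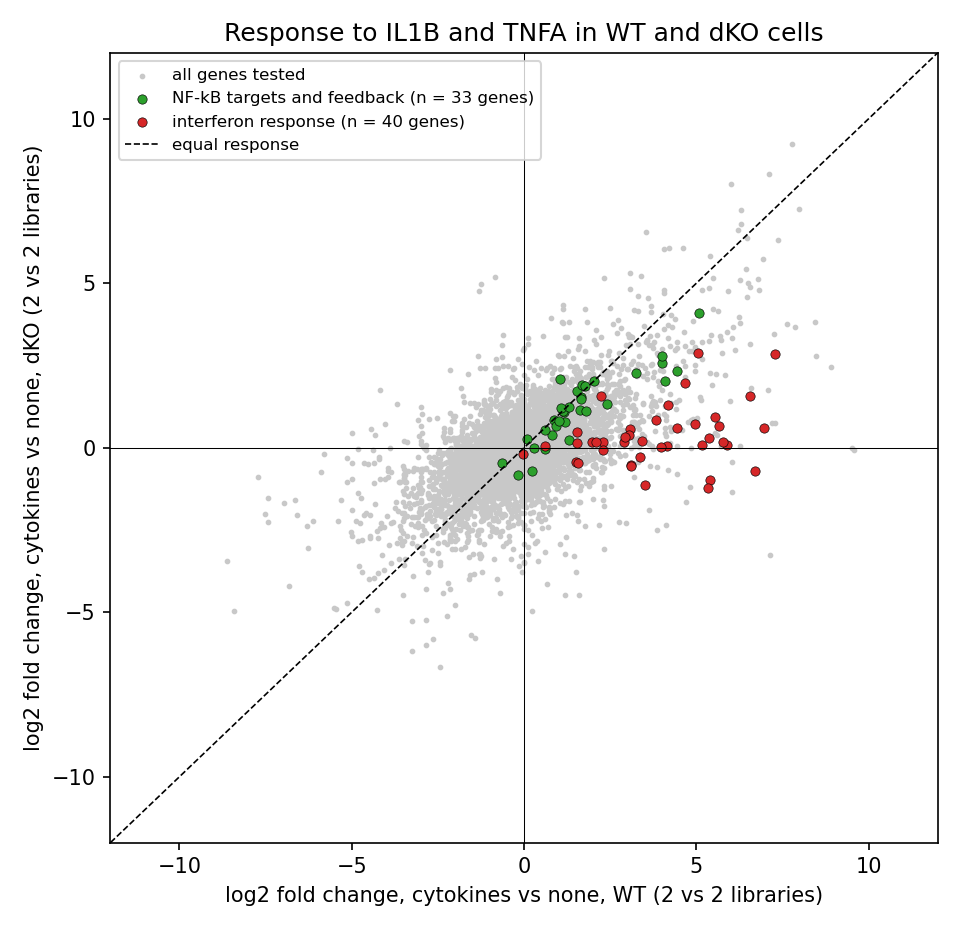
Log2 fold change for cytokines in WT (horizontal) and dKO cells (vertical), each from 2 against 2 libraries, for all 15698 genes tested (grey), 33 NF-kB targets (green) and 40 interferon response genes (red), with a dashed line of equal response. The NF-kB genes had medians of 1.31 in WT and 1.15 in dKO, and the interferon genes of 3.67 and 0.17.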

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

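The interaction tests of the lists were planned, and of the tests of explanations here, those on leukocytes and on the receptor and signalling genes were chosen only after the result was seen. A difference between genotypes in the response to cytokines, by the interaction test of the list, set apart 6 lists. Their median interaction terms on the log2 scale were -3.42 for interferon response, -1.13 for chemokines and cytokines, -0.99 for MHC antigen presentation, -0.45 for glycolysis and hypoxia, -0.28 for NF-kB targets and feedback, and 0.20 for the ETS family without the deleted genes. A term below 0 can reflect a higher level in dKO without cytokines as well as a lower one with them. Median log2 fold changes in dKO against WT were -0.42 without and -3.36 with cytokines for interferon response. They were 0.15 and -0.86 for MHC antigen presentation, 0.57 and -0.01 for chemokines and cytokines, and 0.59 and 0.04 for glycolysis and hypoxia. NF-kB targets had 0.06 and -0.07, and the ETS family -0.20 and -0.08. All 6 calls were lost with an estimated correlation, at adjusted p-values from 0.291 to 0.452. In the fry test NF-kB targets (adjusted p = 0.0237) and glycolysis and hypoxia genes (0.0297) passed. The others did not, with 0.0555 for interferon response.

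The interferon response was the largest of these, with 38 of 40 genes higher after cytokines in WT and 1 of 40 in dKO. Leukocytes in the WT cultures are argued against, since the mean of Ptprc, Tyrobp, Itgam and Laptm5 reached at most 0.363 CPM in the WT libraries with cytokines. A general loss of the receptor and signalling genes before cytokines is argued against for the set of 7, whose median log2 fold change was -0.354 (SE of the mean over genes 0.225), although Jak1, at -0.84 (adjusted p = 0.0382 in edgeR), stays open. Less Ifnb1 transcript in dKO is a candidate explanation, as Ifnb1 had 12 counts over the WT libraries with cytokines (10 and 2) and 0 in all other libraries, but this rests on few counts and could also follow from the weaker response. The genotype itself stays open as untested.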

How the results depend on the processing

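Leaving out both dKO replicate 2 libraries, and the block within genotype for lists and named genes, were chosen only after the results were seen. At an adjusted p of 0.01 the counts of changed genes, in the order of the report, were 868, 701, 90 and 1899, and with a minimum change of 1.5-fold 1021, 676, 156 and 1599, which a stricter threshold explains. With only the 4 libraries of each comparison fitted they were 2266, 4585 and 1 for the first 3. DESeq2 gave 1734 for cytokines in dKO, 372 for the interaction and 4 of 4 Erg and Fli1 tests past 0.05. Without both dKO replicate 2 libraries they were 5602 for dKO against WT without cytokines, 1339 for cytokines in dKO, 193 for the interaction and 4 Erg and Fli1 tests. Without the filter the interaction had 75 genes, and the correlation of the cytokine responses was 0.201, with 0.255 in DESeq2 and 0.432 to 0.531 without single libraries. With the estimated correlation 0 lists passed. Without single libraries the counts ran from 527 to 3675, 413 to 993, 130 to 731, 1621 to 4976 and 0 to 41, and the Erg and Fli1 tests from 0 to 2. Endothelial identity genes for cytokines in dKO turned upward without dKO replicate 2 lacking cytokines (adjusted p = 0.0144), with a range from 0.000439 to 0.734 without single libraries. The cause was not tested for any of these but the stricter thresholds.

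The number block over all libraries, which does not pair across genotypes (correlations 0.02 to 0.13), gave 1351 genes for cytokines in dKO and 3 Erg and Fli1 tests. The block within genotype gave 5943 and 3769 genes for cytokines in WT and dKO and 947 for the interaction, and changed 3 list calls, given above, and no other list call. Lists that passed only in another setting, beside those in the report, were, without the filter, the ETS family for cytokines in dKO (adjusted p = 0.049) and, for the interaction, mesenchymal (0.021) and cell cycle genes (0.0423), and, with the number block, mesenchymal (0.0296) and coagulation genes (0.0297) for dKO against WT with cytokines. Without both dKO replicate 2 libraries these were venous (0.00948) and cell junction genes (0.0104) for dKO against WT without cytokines, and sinusoidal (0.022), venous (0.0153), coagulation (0.0264) and cell junction genes (0.01) with cytokines. They were also coagulation genes for cytokines in WT (0.0376), the ETS family for cytokines in dKO (0.0393), and endothelial identity (0.0325), mesenchymal (0.00847) and p53 genes (0.0367) for the interaction, while hepatocyte markers without cytokines did not pass (0.164). Of 268 named calls, 169 were lost in at least 1 setting and 0 reversed. The calls lost were 0 with DESeq2 size factors, 2 in DESeq2, 5 with the number block, 1 of 116 with the block within genotype and 58 without the filter. With 2 libraries a group and 4 residual degrees of freedom, changes of 2-fold were mostly missed in simulated data (20% called for dKO against WT without cytokines).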

Other observations

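The tests of explanations in this part were all chosen only after the results were seen, while the fits without single libraries were planned. The most abundant transcript differed between the groups. It was Dcn in both WT libraries without cytokines (1.02% and 1.01% of counts), Selp in both given cytokines, Clu in both dKO libraries without cytokines (1.90% and 2.07%), and Saa3 in both given cytokines (2.55% and 1.67%). Saa3, an acute phase gene, had 480.3 and 509.3 CPM in WT without cytokines and 6849 and 7105 with them, against 14140 and 4899 CPM in dKO without cytokines and 28540 and 17730 with them (interaction -2.54, adjusted p = 0.29 in edgeR, and -2.38, adjusted p = 0.0049 with libraries paired within genotype). These genes were chosen after their values were seen.

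Among endothelial transcripts outside the naming rule, Robo4, Sox18 and Stab1 were much lower in dKO replicate 1 than in dKO replicate 2. Robo4 stood at 143 and 200 CPM in WT without cytokines, 0.67 CPM in dKO replicate 1 and 62.9 CPM in dKO replicate 2. Sox18 stood at 144, 172, 1.07 and 84.5 CPM, and Stab1, a scavenger receptor gene of sinusoidal cells, at 1740, 2050, 18.6 and 611 CPM in the same order. All 3 were chosen after their values were seen.

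The dKO replicate 2 libraries lay between WT and dKO replicate 1. RNA or reads of the WT libraries with cytokines mixed into dKO replicate 2 with cytokines are argued against by the interferon genes. Their median share of the WT level was 0.0839 in that library (0.16 against the WT library with the lower levels, and 0.103 in dKO replicate 1). Xist reached 0.376 of its level in WT replicate 2. Such mixing was not tested for dKO replicate 2 without cytokines, where Xist reached 0.354. An effect of sex as seen in WT is argued against, since the WT replicates, 1 with Xist and 1 with Y-linked transcripts, lay at most 0.13 times as far apart on the first principal component as the dKO replicates. Both dKO replicate 2 libraries held Xist and Y-linked transcripts together, the latter at 0.669 without and 0.729 with cytokines of their level in dKO replicate 1. The gap between the WT replicates does not test a library that holds cells of both sexes. Incomplete loss of Erg and Fli1 stays open for the endothelial genes, which recovered by a median of 0.366 and 0.381 of the difference, within 0.0773 of the mean recovery of Erg and Fli1. Cells that kept both genes and responded to cytokines as in the WT cultures are argued against by the same interferon values, while undeleted cells with a weaker response were not tested.

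The fibroblast-associated genes Pdgfra and Col6a1 rose in dKO cells. The sort for CD31 and VE-cadherin should remove stromal cells, but the genes of both markers, Pecam1 and Cdh5, stood lower in dKO without cytokines. Pecam1 had a log2 fold change of -1.8. Cdh5, chosen here after its values were seen, stood at 163 and 587 CPM against 1230 and 1310 CPM in WT. The median of Acta2, Tagln, Cnn1, Myl9, Des, Myh11, Postn, Fap, Thy1 and S100a4 was 0.648 and 0.852 CPM in the dKO libraries without cytokines. In WT it was 0.277 and 0.472 CPM. These medians argue against stromal or contractile cells that carry most of these transcripts. They cannot decide on fibroblasts that carry Pdgfra and lack most of these transcripts. Of the 10, Myl9 stood higher in dKO, at 59.4 and 59.2 against 17.1 and 18.2 CPM, Acta2 at 10.5 and 12.3 against 5.83 and 10.5 CPM, and Thy1 lower, at 6.7 and 31.6 against 90.9 and 128 CPM. A single dKO library as the source of the stromal list's rise is argued against too, as its median log2 fold change was 1.83 without dKO replicate 1 and 1.57 without dKO replicate 2, although the call of Col6a1 was lost without WT replicate 1 (adjusted p = 0.0722) or WT replicate 2 (adjusted p = 0.0656). The genotype stays open as untested.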
